A study of Rattus norvegicus with 5 samples.

How the data were processed

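Lung tissue of Sprague Dawley rats was profiled by RNA sequencing on the Genome Analyzer IIx, per the labels. Total RNA was extracted with TriReagent and made into libraries with an Illumina TruSeq kit, per the labels' protocols. There were 5 libraries, 1 per group: a normoxic male that was not screened, and 4 rats exposed to hypobaric hypoxia, made up of a susceptible, a normal and a tolerant male and a tolerant female. With 1 library per group there was no replicate, so no value has a spread of its own and no test between conditions was possible. A test on the reads of a pair of libraries compares those libraries and not the conditions.

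The authors deposited 11 tables of differentially expressed genes, each comparing 1 library with another, per the file headers and the labels. The 2 tables attached to the tolerant male were byte for byte identical to tables attached to the normal male and were not used, which left 9 distinct tables. They comprise 4 tables against the normoxic library and 5 between exposed libraries. None of the 9 tables compares the tolerant female with the tolerant male, so that comparison was made through derived folds only. Each row holds a gene symbol, a proportional fold change, an FDR-corrected p-value, a chromosome record and a start and end. The deposited fold is a signed ratio of proportions, per the file headers: a positive value is the first library over the reference and a negative value is minus the reference over the first library. The largest number that double precision can hold stands where 1 library was at 0, as read from the values. The FDR-corrected p-value is the authors' own, per the file headers, and an exact 0 stands where it fell below the precision stored. Only genes with a fold of at least 2 and an FDR-corrected p below 0.05 are in the deposited tables, per the file headers and the values. A gene outside a table therefore has no value here, and its absence does not show that it was unchanged. The test behind the p-values, the aligner, the counting and the genome build are not given in the sources used here. The tables hold no counts and no value per library, so the depth is unknown, and no interval or detection floor could be given. Coordinates are printed as the authors' tables give them, on a build that is not named.

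Folds were turned into log2 values with their sign, and each symbol was counted once per table through its row with the largest absolute fold. Symbols starting with LOC, RGD, MGC or id, blank symbols and symbols turned into dates by a spreadsheet (6 rows) were treated as predicted or unnamed. Agreement between tables was checked in 7 sets of 3 tables that link the same 3 libraries: of 171 rows listed in all 3 tables of a set, 171 matched within 0.001 on the log2 scale. Since the folds chain exactly, a fold between libraries that no table lists for a gene was derived, where needed, as the difference of its log2 folds against a shared library. Rows with several gene models at 1 locus were left out of these chains, except for the haemoglobin genes, whose models at a locus were paired in the order of their folds. The derivation was tested on simulated data with 20000 genes, of which 400 were changed, and recovered 828 of 828 rows. All simulated folds came from the same set of levels, so this checks the code and not how reliable a derived fold is. No p-value belongs to a derived fold.

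Symbols were checked against the RefSeq gene table of the rat assembly GRCr8, used for names and chromosomes only. Of 1323 named symbols, 1308 were found there. Of 1319 pairs of symbol and chromosome, 36 (2.73%) lay on another chromosome than in that table. Over the 9 tables, 59 of 1823 loci (3.24%) carried more than 1 symbol. Symbols on another chromosome were kept in all counts and left out of the genes named by size. Where such a symbol is a list member, it is said beside the value.

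Before the data were examined, 32 gene lists (pathways, cell types and gene families) and the rule for named genes were fixed. The rule named the 8 genes with the largest finite fold in each direction of each table against normoxia and the 5 largest in each table between exposed libraries. It also named up to 12 genes listed in all 4 tables against normoxia with the same direction, up to 4 members per list and table, and every listed sex-linked gene. Genes named outside this rule are said to be so. Some genes that the rules for named and flagged genes picked are not reported here, but stay in every count by table or list. For lists with 3 or more listed members, the median log2 fold was placed among the medians of 10000 random sets of the same size from the same table. These percentiles describe the listed genes of that pair of libraries, and the sets could not be matched on expression because the tables give none. Overlaps of the 4 tables against normoxia were set beside a simulation of unchanged libraries that share 1 reference, with 2000000 simulated genes. The number of genes the authors tested is not given, so the overlap of independent lists could not be computed. Intervals for ratios of locus spans are 95% bootstrap intervals over genes with 2000 draws, and genes are not replicates.

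Alternatives were a fold of at least 4, an FDR-corrected p of at most 0.01, leaving out genes with 0 in 1 library, leaving out predicted or unnamed genes and counting every row. Added after the tables had been seen were the overlap without the normal male, lists at an FDR-corrected p of at most 0.01, and leaving out symbols with rows of opposite sign or on another chromosome. The work used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.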

Results

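Transcripts were measured by RNA sequencing in the lungs of 5 Sprague Dawley rats, an outbred laboratory strain. A normoxic male served as the reference. The other 4 rats spent 1 h in a decompression chamber at a simulated altitude of 9144 m, after an earlier screen for the time to the first gasp under hypobaric hypoxia. The susceptible male belonged to the group that gasped before 5 min, the normal male to the group at 15 to 20 min, the tolerant male to the group above 45 min and the tolerant female to the group above 60 min. Each group was 1 library, so no difference below has a replicate check, and depth per library is unknown. The tolerant female was the only female, and the normoxic reference was male. In every comparison of the tolerant female with a male, sex therefore cannot be told apart from tolerance, exposure or the animal. All folds and p-values are the authors' own and compare libraries. The study asked how early transcript responses differ between susceptible and tolerant rats.

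The tables that contained the normal male library were the longest. Against normoxia, the authors' deposited tables held 257 genes for the susceptible male (103 higher, 154 lower), 871 for the normal male (420 higher, 451 lower), 262 for the tolerant male (123 higher, 139 lower) and 249 for the tolerant female (134 higher, 115 lower). Without predicted or unnamed genes the splits were 98 higher and 96 lower, 233 and 372, 111 and 90, and 96 and 92 in the same order in the authors' deposited tables. Over both kinds of comparison, the authors' deposited tables with the normal male had 590 to 1036 genes and those without it 134 to 262. At a fold of at least 4, between 33 and 408 genes per table were left. Genes with near-identical copies, among them haemoglobin, immunoglobulin, RT1, metallothionein and ribosomal protein genes, are uncertain throughout, since the way reads were shared between copies is not given in the sources used here.

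**Figure D1:**
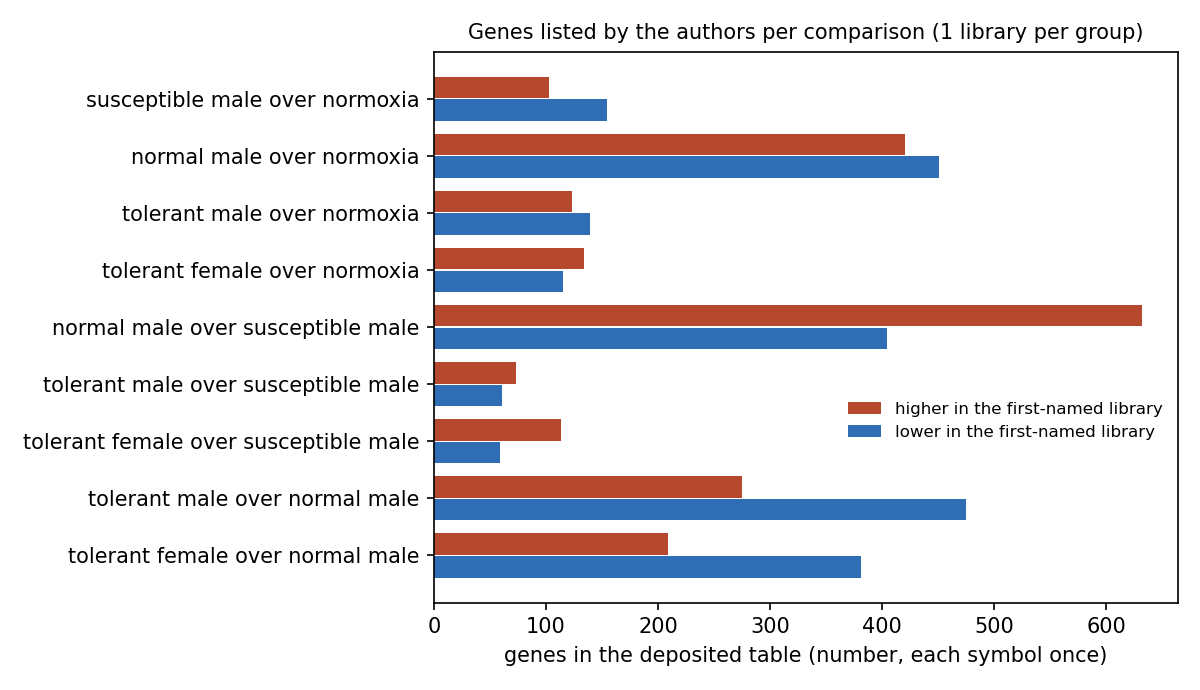
Bars give the number of genes in each of the authors' 9 deposited tables, with each symbol counted once, split into genes higher and lower in the first-named library; the horizontal axis is a count of genes. The 4 tables with the normal male hold 590 to 1036 genes and the other 5 hold 134 to 262.

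Several early-response genes were higher, and heart muscle genes lower, in all 4 exposed libraries than in the normoxic one. Nr4a3, an orphan nuclear receptor of the immediate-early class (chromosome 5, 64713468 to 64753311), was 38.8-fold higher in the susceptible male, 20.1-fold in the normal male, 13.1-fold in the tolerant male and 20.1-fold in the tolerant female in the authors' deposited tables, with FDR-corrected p-values of 1.28e-13, 1.00e-06, 0.00113 and 2.83e-06. Apold1, an early-response gene of endothelial cells (chromosome 4, 171903156 to 171907705), was 21.1-, 6.07-, 17.7- and 23.8-fold higher in the same order in the authors' deposited tables. Plat, which encodes tissue plasminogen activator, was 4.70-, 5.84-, 3.60- and 5.19-fold higher in the authors' deposited tables. The cell-cycle inhibitor Cdkn1a was 17.0-, 4.30-, 10.9- and 8.30-fold higher and Errfi1, a feedback inhibitor of the EGF receptor, 7.33-, 3.70-, 4.19- and 4.77-fold higher in the authors' deposited tables. Both are on the list of glucocorticoid-response genes, of which 5, 5, 5 and 6 were listed, all higher, with medians at percentiles 99.8, 95.3, 99.6 and 99.9 of random sets from the authors' deposited tables. Some lists share members. Among those listed in the susceptible male, Dusp1 is also on the immediate-early list and Lcn2 on the neutrophil list. The results of these lists are thus not separate. Bnip3, a known target of hypoxia-inducible factor, was 2.72-, 3.62-, 2.59- and 2.38-fold higher, whereas Aplnr, the apelin receptor, was 2.87-, 4.31-, 2.08- and 4.73-fold lower in the authors' deposited tables. The goblet cell gene Clca3 was 10.2-, 11.6-, 38.7- and 32.8-fold lower in the authors' deposited tables.

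Cardiac muscle genes stood on the lower side in every table against normoxia. Rat pulmonary veins carry a sleeve of heart-type muscle, so such transcripts can occur in lung tissue. Of the 37 symbols on the cardiac list, the authors' deposited tables held 18 for the susceptible male, 16 for the normal male, 16 for the tolerant male and 17 for the tolerant female, every one lower than in normoxia. Without Myl7 of the tolerant male, which that table lists with 0 at a locus on chromosome 2 while the reference table has the gene on another chromosome, the median of the listed members was 7.55-, 5.92-, 46.7- and 4.08-fold lower in the authors' deposited tables. Mb, the myoglobin gene (chromosome 7, 115087558 to 115094827), was 172-, 6.13-, 874- and 12.6-fold lower, and Myh6, the alpha heavy chain of cardiac myosin (chromosome 15, 33044491 to 33068217), 7.75-, 8.34-, 602- and 4.51-fold lower in the authors' deposited tables. Sln was 12.1-, 3.61-, 419- and 5.37-fold lower and Tnni3 7.92-, 5.72-, 155- and 4.28-fold lower in the authors' deposited tables.

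In all, 59 genes stood in the 4 tables against normoxia, 23 higher in each, 26 lower in each and 10 in opposite directions in the authors' deposited tables. Of the 26 lower in each, 13 were on the cardiac list, Myl7 among them. Pairs of the authors' deposited tables shared 42.4% to 56.6% of the genes of the shorter table, and 71.6% to 99.2% of the shared genes had the same direction. Sharing was highest by direction between the susceptible and tolerant males, with 124 of 125 shared genes in the same direction in the authors' deposited tables, and lowest between the susceptible and normal males, with 78 of 109. All 4 tables use the same normoxic library. Simulated unchanged libraries with 1 shared reference gave a sharing of 9.77% when 1% of genes were listed and 18.6% when 5% were, with 100% and 99.9% in the same direction. Part of the observed overlap may thus come from the reference. The simulation gave every gene the same spread and listed the same share of genes in both tables, unlike the real tables. It therefore cannot say how large that part is.

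**Figure D2:**
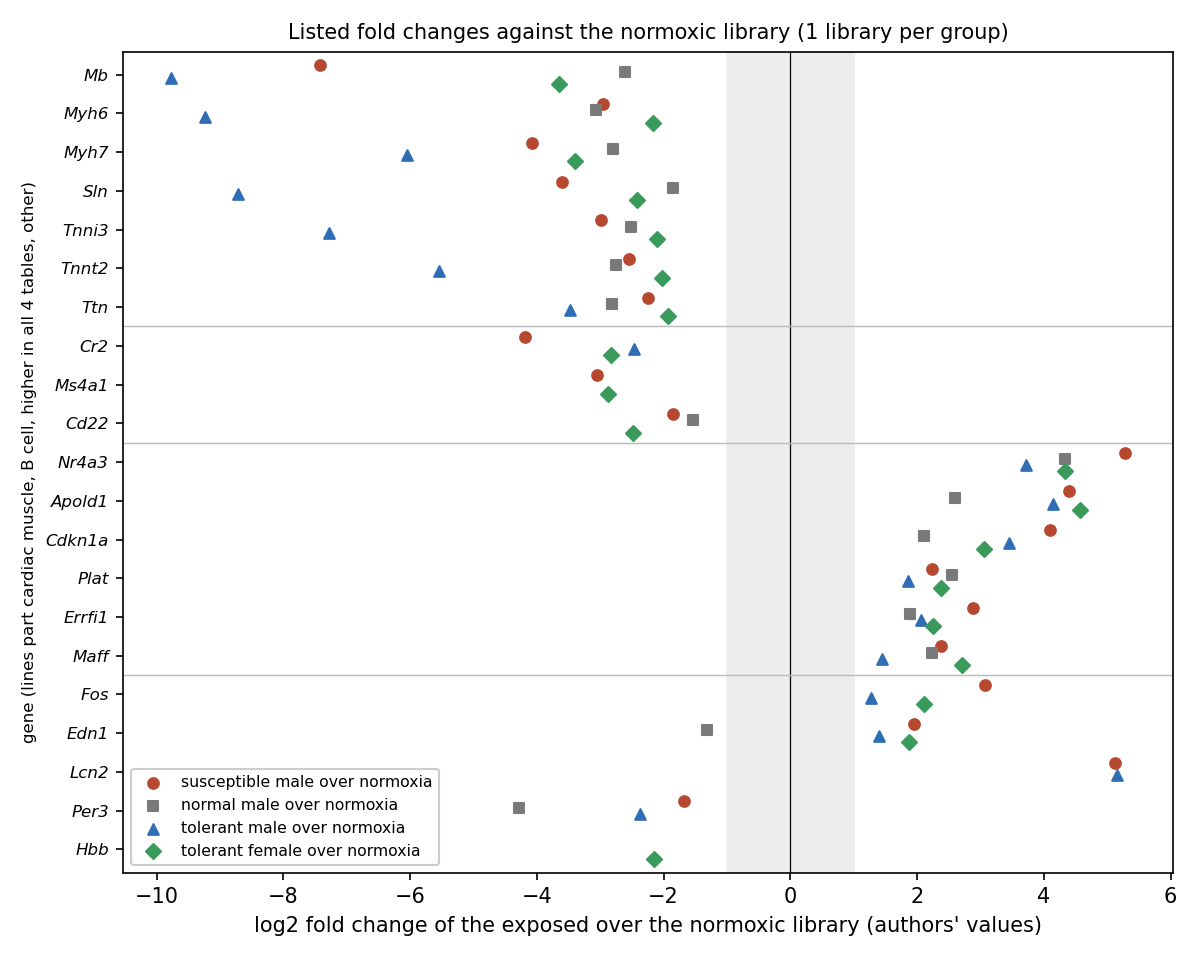
Each point is the log2 fold change of 1 gene (vertical axis) in 1 of the authors' 4 deposited tables against the normoxic library (marker shape and colour); the grey band from -1 to 1 holds no values because the authors listed only folds of at least 2, and a missing point means that the gene was not listed. Heart muscle genes lie furthest to the left in the tolerant male (Mb at -9.77), Nr4a3 and Apold1 lie to the right in all 4 tables, and Edn1 lies to the left in the normal male only.

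Immediate-early and neutrophil granule genes were higher in the susceptible male than in the normoxic male, and B cell genes lower. Of the 33 immediate-early symbols, 13 were listed, all higher, with a median log2 fold of 1.81 at percentile 99.8 of random sets from the authors' deposited table. Besides Nr4a3, the authors' deposited table gave Fos, a subunit of the AP-1 transcription factor, as 8.39-fold, Rgs1 as 7.14-fold and Nr4a1 as 5.58-fold higher. Among 8 listed neutrophil genes 7 were higher, with Lcn2 at 34.8-fold, Ngp at 15.3-fold and Camp at 6.39-fold, and Retnlg was 3.95-fold lower, with the median of the list at percentile 98.3 in the authors' deposited table. Prg2, the major basic protein of eosinophils, was 19.6-fold higher and Pck1, a key enzyme of gluconeogenesis, 24.5-fold higher in the authors' deposited table. All 10 listed B and plasma cell markers were lower, with Cr2 at 18.2-fold, Cxcr5 at 9.90-fold and Ms4a1 at 8.27-fold, and their median log2 fold was -2.65 at percentile 3.93 in the authors' deposited table. The authors' deposited table gave Glycam1 as 97.1-fold lower. Of the 4 listed cytokine and inflammation genes, the follicular chemokine Cxcl13 was 32.0-fold and Ccl19 14.4-fold lower, and the other two, Il1a and Socs3, were higher in the authors' deposited table. Mrgprg was 95.6-fold, Ubd 30.5-fold and Itln1 21.2-fold lower in the authors' deposited table. Clock genes were mixed, with Per3 3.18-fold, Per2 2.35-fold and Tef 2.02-fold lower and Bhlhe40 5.00-fold higher in the authors' deposited table. Edn1, which encodes the vasoconstrictor endothelin 1 (chromosome 17, 28303384 to 28309950), was 3.88-fold, the tissue factor gene F3 3.02-fold and Pfkfb3, a regulator of glycolysis, 2.84-fold higher in the authors' deposited table. The 5 listed cell cycle genes were lower, led by Mcm5 at 5.12-fold and Top2a at 4.88-fold (percentile 34.4 of the list's median), as were the 2 listed interferon-response genes Mx2 (2.59-fold) and Ifi47 (2.56-fold) in the authors' deposited table. Mt2A was 5.18-fold, Il1a 7.36-fold, Socs3 2.36-fold, Txnip 2.91-fold and Inmt 3.14-fold higher, and Scgb3a1 3.29-fold lower, in the authors' deposited table.

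In the normal male, the listed glucocorticoid-response genes and most listed ribosomal protein genes were higher than in the normoxic male. The listed clock genes were lower. The authors' deposited table gave Mt2A, a metal-binding stress protein, as 46.7-fold and, in another gene model, 8.06-fold higher, and Mt1a as 9.75-fold higher. All 5 listed glucocorticoid-response genes were higher, among them Fkbp5 at 4.36-fold, with a median log2 fold of 2.12 at percentile 95.3 in the authors' deposited table. Of 14 listed ribosomal protein genes 12 were higher, with Rps14 at 17.7-fold and Rpl6 at 7.52-fold, in the authors' deposited table. The list's median lay at percentile 93.3. Of 4 oxidative phosphorylation subunits 3 were higher (percentile 71.5), with Cox7a2 at 2.31-fold and Ndufv3 2.97-fold lower, in the authors' deposited table. The random sets were not matched on locus span. Named genes higher in the normal male had a median span 0.583 times that of genes that were lower. A bias of this library towards short genes thus stays open for these lists, here and in its other comparisons. All 6 listed HIF-response genes were higher, including Ndrg1 at 3.02-fold and the mitochondrial gatekeeper kinase Pdk1 at 2.25-fold, with the list's median at percentile 81.5 in the authors' deposited table. Of 23 club and secretory cell markers 3 were listed, all higher (Scgb3a1 3.34-fold, Scgb3a2 2.25-fold, Scgb1a1 2.14-fold; percentile 63.2 of the list's median), as were Hspa1b (3.46-fold), Cxcl1 (5.16-fold), Cxcl9 (3.22-fold), Apln (3.68-fold), Ramp3 (4.19-fold), S100a8 (3.52-fold), Cd14 (3.03-fold), Gclc (3.09-fold) and Nqo1 (2.72-fold) in the authors' deposited table. The largest folds on the higher side also included Traf4 at 34.3-fold, C1qtnf5 at 24.8-fold, Pde10a at 18.4-fold, and Hs1bp3 and Ppp2ca at 24.2- and 18.6-fold, but Hs1bp3 and Ppp2ca had another row that was lower by 3.44- and 4.18-fold in the authors' deposited table. On the lower side stood Elf2 at 45.3-fold, the vessel-remodelling ligand Angpt2 at 41.9-fold, Lrrc10 at 41.8-fold, the scaffold Akap12 at 39.3-fold, Vangl2 at 29.2-fold and the prostacyclin receptor Ptgir at 21.6-fold in the authors' deposited table. The 4 listed clock genes were lower, Per3 (chromosome 5, 168150608 to 168187821) at 19.5-fold, Tef at 4.70-fold, Per2 at 2.62-fold and Cry2 at 2.44-fold, with the list's median at percentile 7.06 in the authors' deposited table. Of 6 listed smooth muscle and fibroblast markers, the collagens Col3a1 (2.72-fold), Col1a2 (2.54-fold) and Col1a1 (2.23-fold) were lower and the other 3 higher in the authors' deposited table. Of 33 immediate-early symbols 4 were listed, all higher (percentile 93.7 of the list's median), while folds derived through other libraries put Fos 1.69-fold and Nr4a1 1.89-fold lower than in normoxia. Of the B and plasma cell markers, 1 was listed, Cd22, at 2.91-fold lower in the authors' deposited table. Slc4a1, the red cell anion exchanger, was 12.4-fold lower, while Hba-a2 had rows of opposite sign, 3.60-fold lower and 2.43-fold higher, as did Aqp4, 2.66-fold lower and 2.50-fold higher, in the authors' deposited table.

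Relative to normoxia, the tolerant male had the deepest values for heart muscle genes, described above, and fewer listed immediate-early genes than the susceptible male (5 against 13). The 5 listed immediate-early genes were all higher, with Maff at 2.73-fold, Fos at 2.42-fold and Atf3 at 2.26-fold beside Nr4a3 and the list's median at percentile 86.5, and their count was 3 at an FDR-corrected p of at most 0.01 in the authors' deposited table. Lcn2 was 35.4-fold, Klra17, a natural killer cell receptor family member, 42.6-fold, the neutrophil-associated Stfa2 7.70-fold and the hormone gene Stc1 9.02-fold higher, and Dsg3, a desmosomal cadherin, 336-fold higher in the authors' deposited table, where the FDR-corrected p of Dsg3 was 0.00991. Of the 4 listed neutrophil genes 3 were higher and Retnlg was 6.79-fold lower, with the list's median at percentile 99.1 in the authors' deposited table. At an FDR-corrected p of at most 0.01 that count was 2. Edn1 was 2.62-fold, Apln 3.08-fold, Npr3 4.70-fold, Pdk4 3.22-fold, Scd1 3.08-fold, Hmox1 2.09-fold and Ifit3 2.99-fold higher in the authors' deposited table. All 5 listed B and plasma cell markers were lower, with Cr2 at 5.54-fold, the immunoglobulin heavy chain gene Igha at 3.83-fold and Igj at 3.09-fold (percentile 15.0 of the list's median), and Ccl19 was 5.63-fold and Mrgprg 96.9-fold lower in the authors' deposited table. The 3 listed clock genes were lower, Per3 at 5.19-fold, Tef at 2.89-fold and Per2 at 2.64-fold (percentile 26.2 of the list's median), together with the cell cycle genes Top2a (2.23-fold) and Mcm2 (2.06-fold) in the authors' deposited table. Beyond Mb, Myh6 and Sln, large folds on the lower side included Actn2 (260-fold), Tnni3 (155-fold) and Srl (119-fold) in the authors' deposited table. Mrgprg, at 96.9-fold, lay between Srl and Myh7 (65.9-fold) there.

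B cell and haemoglobin genes were lower in the tolerant female than in the normoxic male, and immediate-early genes higher. The 7 listed B and plasma cell markers were all lower, with Ms4a1 at 7.37-fold, Cr2 at 7.08-fold and Cd22 at 5.58-fold, and their median log2 fold of -2.48 lay at percentile 0.03 in the authors' deposited table. All 5 listed haemoglobin genes were lower, including Hba-a2 at 5.04-fold and Hbb (chromosome 1, 161618782 to 161620292) at 4.43-fold, with a median log2 fold of -2.23 at percentile 0.79 in the authors' deposited table. Itln1, a lectin of mucus-secreting cells, was 55.0-fold, Eln, which encodes elastin, 4.61-fold, the arterial gap junction gene Gja4 3.20-fold, Cyp1a1 3.30-fold and Sox18 6.58-fold lower in the authors' deposited table. The 5 listed cell cycle genes were lower, Top2a at 4.33-fold and Mcm5 at 3.05-fold among them, with the list's median at percentile 18.2 in the authors' deposited table. On the higher side, the authors' deposited table gave Vsig4, a complement receptor of macrophages, as 24.8-fold, Ly6al as 18.6-fold, Cd300lg as 16.1-fold, Mt2A as 9.06-fold, Crem as 8.86-fold, Kcnj15 as 5.89-fold and Mt1a as 5.33-fold higher. The 6 listed immediate-early genes were higher, with Maff at 6.54-fold, Atf3 at 5.35-fold and Fos at 4.31-fold (percentile 99.5 of the list's median), and Il1a was 3.73-fold, Edn1 3.68-fold, Apln 3.48-fold, Bhlhe40 3.06-fold, Pfkfb3 2.51-fold, Hspa1a 2.46-fold and F3 2.05-fold higher in the authors' deposited table. The only listed sex-linked gene in the 9 tables was Ddx3y, 2.05-fold higher in this library in the authors' deposited table. That row lies on the X chromosome record, so it does not measure a Y-linked gene, and the sex of this library could not be checked from the tables used here.

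Between exposed rats, B cell genes were higher in the normal than in the susceptible male, and immediate-early genes lower. The authors' deposited table held 1036 genes, 632 higher and 404 lower in the normal male. All 9 listed B and plasma cell markers were higher, with Igj at 29.6-fold in 1 gene model, Cr2 at 14.0-fold, Igha at 9.93-fold and Cxcr5 at 8.26-fold, and their median log2 fold of 2.92 was at percentile 97.0 in the authors' deposited table. Glycam1 was 172-fold, Cxcl13 77.0-fold, Ccl19 13.3-fold and Cxcl9 8.97-fold higher in the authors' deposited table. The 7 listed cell cycle genes were higher, Kif2c at 13.8-fold, the mitotic kinase Plk1 at 12.9-fold and Rrm2 at 7.75-fold, with the list's median at percentile 86.7, as were the 6 listed interferon-response genes (percentile 73.6), led by the MHC class II genes RT1-Bb (3.22-fold) and RT1-Da (3.14-fold) in the authors' deposited table. All of these 6 except Ifi47 were RT1 (MHC) genes. Of 20 listed ribosomal protein genes 18 were higher (percentile 74.5 of the list's median), and of 10 oxidative phosphorylation subunits 9 (percentile 51.1), with Ndufc1 at 3.42-fold and Ndufs5 at 3.09-fold in the authors' deposited table. Rps2 had rows at 170-fold higher and 6.01-fold lower in the authors' deposited table. C1qtnf5 was 76.8-fold, Zscan12 51.1-fold, Mb 28.1-fold and Scgb3a1 11.0-fold higher in the authors' deposited table. Of 12 listed immediate-early genes 11 were lower, with Fos at 14.1-fold, Nr4a1 at 10.5-fold, Nr4a2 at 8.48-fold and Rgs1 at 6.30-fold, and the median log2 fold of -1.62 lay at percentile 0.17 in the authors' deposited table. Pck1 was 43.5-fold, Elf2 30.4-fold, Angpt2 28.0-fold, Slc4a1 16.9-fold, the eosinophil peroxidase gene Epx 15.4-fold, Bhlhe40 14.4-fold, Edn1 9.69-fold, Camp 7.31-fold, Ngp 7.03-fold and Per3 6.11-fold lower in the authors' deposited table.

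Tolerant against susceptible males showed fewer listed genes. The authors' deposited table held 134, 73 higher and 61 lower in the tolerant male. All 9 listed immediate-early genes were lower, with Nr4a1 at 8.34-fold, Junb at 5.48-fold, Rgs1 at 3.57-fold and Fos at 3.46-fold, and a median log2 fold of -1.56 at percentile 2.56 in the authors' deposited table. The inflammation genes Il1a (3.69-fold) and Socs3 (2.39-fold), Ngp (5.81-fold), Prg2 (7.52-fold), Txnip (2.60-fold), Inmt (5.94-fold) and the hypoxia-inducible Ddit4 (2.01-fold) were lower too in the authors' deposited table. Heart muscle genes were lower again, Myh6 at 77.6-fold, Tnnt2 at 7.98-fold and Ankrd1 at 2.53-fold (percentile 0.77 of the list's median), and Pdia5 was 14.9-fold, Fam111a 14.3-fold and Dlk1 8.88-fold lower in the authors' deposited table. On the higher side stood Stfa2 at 55.6-fold, Klra17 at 34.2-fold, RT1-T24-3 at 14.4-fold and Fcnb, a pattern-recognition lectin of myeloid cells, at 5.19-fold in the authors' deposited table. All 4 listed B and plasma cell markers were higher, with Ms4a1 at 6.13-fold, Cd79b at 3.86-fold and Cd79a at 2.65-fold and the list's median at percentile 95.7, and 1 of them remained listed at an FDR-corrected p of at most 0.01 in the authors' deposited table. The 4 listed interferon-response genes were higher, Mx1 at 2.75-fold, Ifi47 at 2.66-fold, Irf7 at 2.20-fold and Mx2 at 2.10-fold (percentile 78.0 of the list's median), together with Cpa3 (3.39-fold), Zbtb16 (3.23-fold), Scd1 (2.63-fold) and Apln (2.07-fold) in the authors' deposited table.

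The tolerant female had lower neutrophil granule and red cell genes than the susceptible male. Of 172 genes in the authors' deposited table, 113 were higher and 59 lower. With predicted or unnamed genes left out, 83 remained in the authors' deposited table, and the split turned to 33 higher and 50 lower. All 7 listed neutrophil genes were lower, with Ngp at 47.6-fold, Camp at 20.4-fold, Lcn2 at 18.3-fold and the matrix protease gene Mmp9 at 7.47-fold, and their median log2 fold of -2.90 lay at percentile 0.01 in the authors' deposited table. All 7 listed red cell genes were lower, including Slc4a1 at 14.2-fold and Hba-a2 at 6.15-fold, with a median log2 fold of -2.62 at percentile 0.025 in the authors' deposited table. Prg2 was 44.0-fold, Mlc1 21.6-fold, Eln 8.64-fold, Rps2 6.46-fold, Nr4a1 4.24-fold, Cyp1a1 3.72-fold and Npas2 3.46-fold lower in the authors' deposited table. Of the B and plasma cell markers 2 were listed, Igj at 11.5- and 10.1-fold higher in 2 gene models and Igha at 5.88-fold higher, and outside that list Igkv28 was 19.8-fold and Igh-1a 17.8-fold higher in the authors' deposited table. Of 3 listed clock genes, Dbp (4.95-fold) and Per2 (3.07-fold) were higher in the authors' deposited table. Cd300lg was 42.1-fold, Vsig4 28.2-fold, Ly6al 18.7-fold, Cxcl9 7.71-fold, Zbtb16 4.39-fold and Fkbp5 2.24-fold higher in the authors' deposited table. The row named Mx1, 4.21-fold higher in the authors' deposited table, lies on chromosome 1, where the reference table does not place that gene.

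Compared with the normal male, the tolerant male had lower heart muscle genes. The authors' deposited table held 750 genes, 275 higher and 475 lower, and 469 without predicted or unnamed genes, of which 225 were higher and 244 lower. Akap12 was 74.0-fold, RT1-T24-1 53.9-fold, Elf2 41.2-fold, Angpt2 32.9-fold, Edn1 6.55-fold, Fos 4.09-fold, Col3a1 2.63-fold and Fn1, which encodes fibronectin, 2.12-fold higher in the authors' deposited table. All 8 listed cardiac genes were lower, with a median below that of every random set, Mb at 142-fold, Myh6 at 72.2-fold and Cox6a2 at 37.3-fold, while Myl7 was listed with 0 in the tolerant male in the authors' deposited table. C1qtnf5 was 311-fold, the mucosal receptor Gp2 281-fold, Glycam1 79.2-fold, the airway secretory gene Plunc 55.6-fold, Scgb3a1 28.1-fold, Cxcl13 23.6-fold and Inmt 12.3-fold lower in the authors' deposited table. The 5 listed B and plasma cell markers were lower, Igj at 10.8-fold and Cr2 at 4.24-fold among them (percentile 20.5 of the list's median), as were 4 of 5 club and secretory cell markers (percentile 70.7), 15 of 16 ribosomal protein genes (43.5) and all 5 oxidative phosphorylation subunits (67.1), so these lists did not stand apart from random sets of the table, in the authors' deposited table. Of 9 interferon-response genes 5 were lower, led by the class II gene RT1-Bb at 3.69-fold, and 4 were higher, led by Ifit3 at 3.71-fold, in the authors' deposited table. The 5 lower were all RT1 genes, and the 4 higher were Mx1, Mx2, Ifit2 and Ifit3. Nos3, the endothelial nitric oxide synthase gene, was 2.52-fold and Ramp3 4.54-fold lower in the authors' deposited table.

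In the tolerant female, clock genes were higher than in the normal male and B cell genes lower. The authors' deposited table held 590 genes, 209 higher and 381 lower, and 376 without predicted or unnamed genes, of which 167 were higher and 209 lower. All 7 listed clock genes were higher, with the output regulator Dbp at 20.8-fold, Per3 at 13.7-fold, Bhlhe40 at 12.8-fold and Tef at 4.01-fold, and a median log2 fold of 2.00 at percentile 99.4 in the authors' deposited table. Of 6 immediate-early genes 5 were higher, with Fos at 7.27-fold, Egr1 at 3.87-fold and Dusp1 at 3.62-fold (percentile 98.5 of the list's median), and Edn1 was 9.18-fold, Il1a 2.79-fold and Pfkfb3 2.63-fold higher in the authors' deposited table. Akap12 was 62.7-fold, Ly6al 36.8-fold, Angpt2 32.7-fold and Vsig4 21.6-fold higher, while Elf2 had rows at 45.3-fold higher and 2.16-fold lower in the authors' deposited table. All 6 listed B and plasma cell markers were lower, Ms4a1 at 6.73-fold and Cr2 at 5.43-fold among them (percentile 4.51 of the list's median), and so were all 5 listed neutrophil genes (percentile 7.12), Lcn2 at 34.4-fold and Mmp9 at 5.50-fold, in the authors' deposited table. The 5 listed cell cycle genes were lower, Kif2c at 11.9-fold and Plk1 at 9.40-fold (percentile 14.9 of the list's median), with 14 of 15 ribosomal protein genes (26.2) and 5 haemoglobin genes (39.7), Hbb at 3.33-fold, in the authors' deposited table. Itln1 was 65.0-fold, C1qtnf5 54.7-fold, Hs1bp3 40.8-fold, Ifit1lb 33.2-fold, Plunc 27.9-fold, Cxcl13 12.4-fold and Eln 4.85-fold lower in the authors' deposited table.

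Alveolar and ciliated cell markers were little represented. No table held a thymocyte marker or a mitochondrially encoded gene. Across the 9 authors' deposited tables, alveolar type II markers were limited to Chia and Etv5, alveolar type I markers to Akap5 and Igfbp2, ciliated cell markers to Ccdc113 and a row named Spag6 that lies on another chromosome than in the reference table, and skeletal muscle genes to Neb. Smooth muscle and fibroblast markers were listed in every one of these tables. At most 6 of 21 were listed (3 higher and 3 lower, in the normal male over normoxia) in the authors' deposited tables. Club and secretory cell markers (at most 5 of 23) and endothelial markers (at most 2 of 18) were listed in some of the authors' deposited tables and absent from others. Zap70 and Prf1 were the only T and natural killer cell markers, with Zap70 2.38-fold higher and Prf1 2.41-fold lower in the normal male than in normoxia in the authors' deposited table.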

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

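The test of locus spans was set down before its result was seen, and the test of gene models afterwards. With 1 library per group, none of the differences between groups here was tested. Several genes were higher than normoxia in 1 exposed library and lower in another, and they are named here because of that. Between its highest and lowest listing against normoxia, Cxcl13 spanned 6.27 on the log2 scale, from 2.40-fold higher in the normal male to 32.0-fold lower in the susceptible male in the authors' deposited tables. Spry4, a feedback inhibitor of growth factor signalling, spanned 4.15, from 2.66-fold higher in the tolerant female to 6.66-fold lower in the normal male in the authors' deposited tables. Scgb3a1 spanned 3.46, from 3.34-fold higher in the normal male to 3.29-fold lower in the susceptible male in the authors' deposited tables. Edn1 spanned 3.28, from 3.88-fold higher in the susceptible male to 2.50-fold lower in the normal male in the authors' deposited tables. Rpl27a spanned 3.16, from 2.39-fold higher in the normal male to 3.73-fold lower in the tolerant male in the authors' deposited tables. Fcnb spanned 2.68, from 2.96-fold higher in the tolerant male to 2.16-fold lower in the normal male in the authors' deposited tables. A further 28 predicted or unnamed loci also went both ways.

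The normal male library took part in the 4 longest tables. Reads split differently among gene models of 1 symbol stay open: 1.72% of the symbols in the table against normoxia had rows of opposite sign, but a gene model that stayed under the authors' cut is not seen in the table. A bias towards short genes in that library stays open: named genes higher in the normal male than in normoxia had a median locus span 0.583 times that of genes that were lower (95% bootstrap interval 0.460 to 0.750), which missed the bound of 0.5 set for the ratio, with the interval reaching past the bound of 0.67 set for its upper end. The same ratio was 0.431 over the susceptible male, 3.51 for the tolerant male over the normal male and 2.94 for the tolerant female over the normal male, and 0.650 to 1.92 in the tables without the normal male. A difference in the rat itself was not tested and cannot be told apart from the library with 1 library per group.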

How the results depend on the processing

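The alternatives without the normal male, with symbols of opposite sign or on another chromosome left out, and for lists at an FDR-corrected p of at most 0.01 were chosen after the data had been seen. All counts are from the authors' deposited tables and carry no test of their own. At a fold of at least 4, the tables against normoxia held 132 genes (susceptible male), 315 (normal male), 87 (tolerant male) and 79 (tolerant female). Over the susceptible male they held 408 (normal male), 33 (tolerant male) and 111 (tolerant female), and over the normal male 336 (tolerant male) and 214 (tolerant female). Fewer genes pass by construction. At that fold 13 genes stood in all 4 tables against normoxia in the same direction, 4 higher and 9 lower, in place of 49. Without the normal male, 76 did so in the other 3 tables, 32 higher and 44 lower. Without predicted or unnamed genes the count fell from 172 to 83 (tolerant female over susceptible male), from 750 to 469 (tolerant male over normal male) and from 590 to 376 (tolerant female over normal male). At an FDR-corrected p of at most 0.01 the tolerant male over normoxia had 3 immediate-early genes (5 before) and 2 neutrophil genes (4 before), and over the susceptible male 1 B cell marker (4 before). The splits by direction changed with the predicted genes, as the higher count of the normal male over normoxia fell from 420 to 233, the lower count of the susceptible male over normoxia from 154 to 96 and that of the tolerant male from 139 to 90. Over the susceptible male, the normal male had 365 higher and 338 lower (632 and 404 before) and the tolerant male 63 and 52 (73 and 61 before). At a fold of at least 4 the larger side changed in 3 tables, to 177 higher and 138 lower for the normal male over normoxia (420 and 451 before), 38 and 41 for the tolerant female over normoxia (134 and 115 before) and 13 and 20 for the tolerant male over the susceptible male (73 and 61 before). All other totals, both directions together, stayed within 1.5 times their first value: 52 at the stricter p, 56 without genes at 0 in 1 library, 6 without predicted genes, 9 with every row counted, 55 without symbols of opposite sign and 55 without symbols on another chromosome. Without genes at 0 in 1 library, the 46 medians of lists moved by less than the standard deviation of their members. Only the cardiac medians of the tolerant male changed, from -5.63 to -5.54 over normoxia and from -4.99 to -4.76 over the normal male (log2). The other lists held no gene at 0, so their medians could not move.

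Not run were the filters on low values, the log2 ratio with a pseudocount and random sets matched on expression, because the tables give no value per library. No paired analysis was possible because each group is 1 library and no test compares groups. For the same reason there was no library to leave out within a group. The depth is unknown, so its limit on any fold could not be stated.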

Other observations

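All tests in this part were chosen after the results they bear on had been seen. The tolerant female and tolerant male can be compared through a shared library, since folds chain exactly between tables. Of 518 gene rows with a derived fold, 131 differed by at least 2-fold, 115 higher and 16 lower in the female, but only 33 of the higher and 10 of the lower rows carry a gene name and the others are predicted or unnamed loci. Heart muscle genes led, with Myh6 134-fold, Sln 78.0-fold, Mb 69.4-fold and Tnni3 36.1-fold higher in the female. The mucosal gene Gp2 was 92.2-fold, the immunoglobulin gene Igh-1a 23.6-fold, Cd300lg 23.3-fold, Glycam1 15.3-fold, Cyp2a3a 13.1-fold, Scgb3a1 6.44-fold, Inmt 5.36-fold and Igj 4.21-fold higher. Lower in the female were the granule genes Ngp (8.20-fold) and Prg2 (5.86-fold), the retinoic acid hydroxylase Cyp26b1 (7.21-fold), Mlc1 (4.35-fold) and the apelin receptor Aplnr (2.27-fold). These genes were picked by size after their values were known, and genes listed in only 1 linking table have no derived fold. With 1 library of each, a difference of sex cannot be told apart from a difference between the animals or the pieces of lung.

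Immunoglobulin loci at the end of chromosome 6 (138246241 to 139765543, between the outermost listed immunoglobulin heavy chain genes) mostly went in the direction of the listed B cell markers, except in the normal male over normoxia, where the only listed marker, Cd22, was lower. Igha is on the B cell list and marks the start of this interval, which was drawn after the values were seen. The shared direction is thus not separate support. Of the predicted loci in this interval, 7 of 7 were lower in the susceptible male than in normoxia, at a median of 8.05-fold, in the authors' deposited table. In the normal male 6 of 6 were higher than in normoxia, at a median of 15.7-fold, in the authors' deposited table. Over the susceptible male, 16 of 16 were higher in the normal male and 5 of 5 in the tolerant female, at medians of 25.1- and 18.4-fold in the authors' deposited tables. Against normoxia 3 of 3 were lower in the tolerant male and 4 of 5 in the tolerant female. All medians here are over the predicted loci alone. Such loci are near-identical copies, and the share of reads between them is unknown.

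Heart muscle genes were lower in every exposed library than in the normoxic one, by medians of 7.55-fold in the susceptible male, 5.92-fold in the normal male, 46.7-fold in the tolerant male and 4.08-fold in the tolerant female. A candidate explanation is more heart-type muscle in the normoxic piece of lung and least in the tolerant male piece. A difference in the share of 1 tissue would move its genes in 1 direction between any pair of libraries. Of 86 folds of cardiac genes derived between pairs of exposed libraries, 1 ran against the median of its pair by more than 1 on the log2 scale. Some pairs were split by direction, with 6 higher and 8 lower in the susceptible than in the normal male and 7 and 7 in the normal male against the tolerant female, and sizes were unequal, from 0.46 to 6.28 between the susceptible and tolerant males. With 1 library per group it is unknown whether noise gives as much, so this stays open. A response of lung cells to hypoxia cannot be told apart from it for these genes, because normoxia rests on 1 rat and 1 piece of lung. That rat was also the only one not screened. The medians lay 3.52 apart on the log2 scale although the exposure was equal, and they neither rose nor fell steadily with the time to the first gasp.

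B cell genes were lower in the susceptible male than in normoxia. Haemoglobin genes did not point to less blood in that piece of lung. Through the tolerant female, 7 rows of 5 symbols gave a derived median log2 fold of 0.19 for the susceptible male over normoxia. The range was 0.13 to 0.37. These genes are near-identical copies with unknown sharing of reads, and models at a locus were paired in the order of their folds. The values argue against less blood only as far as haemoglobin reads can be compared between these libraries. Less lymphoid tissue in the piece may remain open. Glycam1 and Cxcl13, named for the size of their folds, and Ccl19, named from the cytokine list, were lower too. None of them was taken from a list of lymphoid tissue genes. Of 20 T and natural killer cell markers 0 were listed in that table, and 2 had a fold derived through the normal male, Zap70 at 1.67-fold and Prf1 at 1.06-fold lower, which are too few to decide. A response of the susceptible rat itself was not tested.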
